A study of Mus musculus with 4 samples.

How the data were processed

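Messenger RNA was measured by paired-end Illumina sequencing in 4 libraries of mouse oocytes of the ICR strain, per the labels' protocols. Each library came from 60 oocytes or embryos, lysed together, of females 21 to 23 days old. The protocols name PMSG and hCG, the hormones that drive follicle growth and meiotic resumption. The sample titles do not say which of these hormones applied to each library. The series' design text speaks of single oocytes, and the treatment text names Btg4-/- rather than Erk-/- females. Groups were therefore taken from each sample's title, which gives genotype (wild type or Erk-/-) and stage. The stages are GV (germinal vesicle, before meiosis resumes) and MII (metaphase of the second meiotic division, the mature egg). There was 1 library per group and 4 groups.

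The authors deposited FPKM, fragments scaled to transcript length and to the library's mapped total, with a lower and an upper confidence bound per gene, per the file headers. Per the submitters' processing notes, CASAVA 1.8, TopHat and mouse genome build mm9 were used. The program that computed FPKM, its gene annotation and version, the confidence level of the bounds and the treatment of reads that map to several places are not given in the sources used here. The labels do not say whether mRNA was selected by its poly(A) tail or whether the libraries kept strand. Reads from genes with near-identical copies or processed pseudogenes (ribosomal proteins, Gapdh, Actb, several Nlrp genes) may be split in ways that cannot be checked from the values.

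FPKM holds no counts, so the depth of each library is unknown. The width of the authors' bounds gives a relative depth over 2500 genes. Against the wild-type GV library it was 0.807 for Erk-/- GV, 1.04 for wild-type MII and 1.01 for the library labelled Erk-/- MII. Among genes of at least 10 FPKM, the median half-width of the bounds was 8.83% of the value in wild-type GV, 9.74% in Erk-/- GV, 8.15% in wild-type MII and 8.69% in the MII library labelled Erk-/-. The bounds cover uncertainty within a library and not the spread between animals or batches of oocytes. The deposited value lay above its own upper bound in 1018, 796, 709 and 761 rows of these libraries, in that order, and no bounds are quoted for such values. Each file held 23813 rows for 23309 gene symbols. The 260 symbols on several rows (504 extra rows) were summed per symbol. Locus starts in the files count from 0, judged by transcript length (9170 of 21279 genes of matching symbol against 558 for the other reading), so 1 was added to each start.

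Expression was compared as log2((FPKM + 1)/(FPKM + 1)), which understates the change of low genes, over the 9990 genes with a mean of at least 1 FPKM across the 4 libraries. A ratio of at least 2-fold on this scale was counted as higher or lower. This is a rule of size, because with 1 library per group none of the comparisons made here can be tested and no p-value is given. Of the 9990 genes, 3023 were listed at 0 in at least 1 library. An exact 0 can be a failed estimate, so such genes are described as listed at 0 and no fold is given against them. The comparisons were MII against GV within each genotype, labelled Erk-/- against wild type within each stage, and the difference between the 2 maturation ratios (labelled Erk-/- minus wild type). Folds quoted for single genes are ratios of FPKM without the added 1.

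Before the data were examined, 23 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The rule took protein-coding genes found once in the files, with at least 10 FPKM in a library compared. It named the 8 highest and 8 lowest log2 ratios for wild-type maturation, for genotype at MII and for the difference of maturation ratios, and the 5 highest and 5 lowest for the remaining comparisons. It added up to 4 members of each list with the largest absolute ratio, and 18 genes in every comparison (Mapk3, Btg4, Cnot7, Cnot6l, Cpeb1, Dazl, Mos, Ccnb1, Zp1, Zp2, Zp3, Gdf9, Bmp15, Padi6, Nlrp5, Gapdh, Actb and 1 gene not reported here). This names 95 to 107 genes per comparison, of which those that bear on each gene group are described.

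For each list the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile describes these libraries and is not a test. The lists cover the targeted genes, the MAPK cascade, ERK-induced transcripts, CCR4-NOT, decapping and decay, poly(A) and translation factors, zona pellucida and secreted factors, maternal-effect genes, oocyte transcription factors, CDK1 and cyclins, the anaphase-promoting complex and checkpoint, spindle, mRNAs translated during maturation, respiratory chain, ribosomal proteins, mitochondrially encoded proteins, proteasome, chromatin modifiers, stress and apoptosis, granulosa and cumulus cells, other ovarian and blood cells, the early embryo, and reference genes. The list called oocyte transcription factors also holds receptor genes (Kit and Gpr3). None of the 13 mitochondrially encoded genes was among the symbols used, and 12 genes stood on more than 1 list.

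The alternatives were a pseudocount of 0.1 or 5, a mean of at least 10 FPKM, no filter on low values, rescaling to TPM, median-of-ratios scaling, leaving out model names and ribosomal proteins, the highest row per symbol, and picking lowered genes on the ratio of 1 genotype alone. Added after seeing the data were a run without genes listed at 0 in any library and a run with the mean of both GV libraries as baseline, and other limits on FPKM for the test of mixed stages. The counting steps were tested on simulated data with 200 of 9990 genes set 3 log2 units apart in the comparison of wild-type MII with GV. At a noise SD of 0.2 and 0.5 (log2), 94% and 93% of the lowered genes and 100% of the raised genes passed the 2-fold rule, and 0.0102% and 10.3% of unaltered genes did. Both noise levels lie below the spread between the GV libraries (SD 1.60 over genes), which also holds genotype differences. The simulation had no genes listed at 0. These rates therefore check the counting steps and do not estimate errors in the counts below. Motifs were searched in the last 100 nt of the longest annotated 3' UTR of GENCODE release M21, matched by symbol, with no coordinates carried between builds. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.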

Results

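The series measured mRNA in fully grown (GV) and mature (MII) mouse oocytes, wild type or labelled Erk-/-, with 1 library of 60 cells for each of the 4 combinations. Fully grown oocytes make almost no new mRNA and rely on stored maternal mRNA, and the title of the series asks how its degradation depends on ERK. FPKM summed to 453226 in wild-type GV, 420889 in Erk-/- GV, 401160 in wild-type MII and 414167 in the MII library labelled Erk-/-. Genes of at least 10 FPKM numbered 5682, 5543, 3570 and 4397 in the same order, and the 10 most abundant genes took 8.13%, 6.85%, 13.3% and 11.2% of the summed FPKM. No group has a replicate, so every difference below is between single libraries. FPKM is relative to each library's own total and does not measure mRNA per oocyte.

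The targeting was examined first. Mapk3, which encodes ERK1 (mm9 chromosome 7, 133903140 to 133909330), had 333 FPKM in wild-type GV and 52.3 in Erk-/- GV (44.3 to 54.5). At MII it had 25.7 in wild type (21.5 to 27.2) and 34.3 in the library labelled Erk-/- (28.9 to 35.4), and under median-of-ratios scaling the order of these values turned (log2 ratio 0.40 as deposited, -0.04 scaled). The whole-gene Mapk3 value therefore does not go with the genotype label at MII. The labels do not say which exons were removed, and gene-level FPKM cannot show this, so the mature library is called the MII library labelled Erk-/- throughout.

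In wild-type oocytes, transcripts of the egg coat and of the maternal proteins stored for the embryo were far lower at MII than at GV. Padi6, needed to build the cytoplasmic lattices of the oocyte (chromosome 4, 140283270 to 140298558), went from 4264 FPKM in the GV library to 58.7 in the MII library (52.0 to 59.7), 72.7-fold lower. The zona pellucida glycoprotein genes Zp2 (chromosome 7, 127275875 to 127288804), Zp3 (chromosome 5, 136455975 to 136464494) and Zp1 (chromosome 19, 10988787 to 10995091) stood at 2.93%, 3.16% and 4.85% of their GV levels. Some transcripts of the machinery that removes poly(A) tails were higher instead, though the CCR4-NOT list was mixed (6 of 16 higher, 7 lower). Btg4, the adaptor that brings the CCR4-NOT deadenylase to maternal mRNA (chromosome 9, 50924106 to 50927805), had 216 FPKM at GV and 2987 at MII, and the deadenylase gene Cnot7 (chromosome 8, 41577892 to 41601201) had 53.4 (50.2 to 56.9) and 459 (452 to 475).

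**Figure D1:**
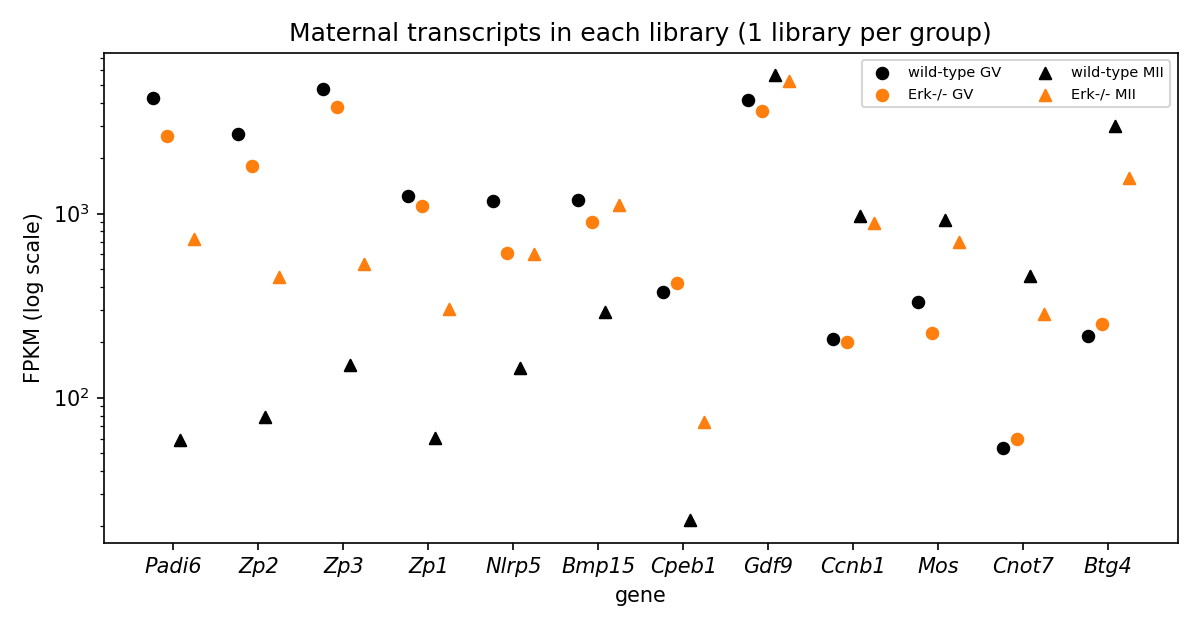
FPKM (log scale) of 12 genes named in every comparison, with 1 point per library: circles are GV, triangles MII, black wild type and orange labelled Erk-/-. Padi6 lies at 58.7 in wild-type MII and at 727 in the MII library labelled Erk-/-, while Btg4 is above its GV level in both.

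Of 9990 genes, 4952 were at least 2-fold lower and 2054 at least 2-fold higher in wild-type MII than in wild-type GV, with a median log2 ratio of -0.97. Among maternal-effect genes, 16 of 23 were lower and 5 higher (median -2.30, against -0.09 in random lists matched on expression, percentile 0.66). The histone chaperone gene Npm2 was 50.7-fold lower and Nlrp14 27.7-fold lower, and Nlrp5, a core part of the subcortical maternal complex, went from 1172 to 145 FPKM. In the list of zona and secreted factors, 6 of 9 were lower and 1 higher. The secreted growth factor gene Bmp15 was at 24.6% of its GV level, while its partner Gdf9 was at 136% (4139 and 5635 FPKM). Ribosomal protein genes were lower in 67 of 75 and higher in 1 (median -3.30, percentile 0), as with Rps15 (633 FPKM at GV and 0.504 at MII) and Rps4x (358 and 0.125). Proteasome subunits were lower in 25 of 31 and higher in 2 (median -3.56, percentile 0), and Psma6 went from 84.4 to 0.214 FPKM. Respiratory chain subunits were lower in 49 of 75 and higher in 1 (median -1.95, percentile 0.15), and Uqcrq and Cox7c, at 436 and 405 FPKM in GV, were listed at 0 in MII.

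Messages that the literature describes as translated during maturation stood out in the other direction in wild type. Of 13 such genes, 12 were higher at MII and none lower (median 1.74, against -0.06 in matched random lists, percentile 99.7). They include Ccnb1, the cyclin that activates CDK1, at 467% of its GV level, Mos, the kinase that starts the oocyte's MAPK cascade, at 276%, and Plat, the plasminogen activator, 8.44-fold higher. Btg4, Cnot7 and Cnot6l also belong to the CCR4-NOT list, where 6 of 16 genes were higher and 7 lower. The scaffold gene Cnot1 was 13.0-fold lower (34.8 and 2.68 FPKM). Among poly(A) and translation factors 17 of 29 were lower and 5 higher (median -1.88, percentile 4.82). Cpeb1, whose protein binds the element that drives cytoplasmic polyadenylation (chromosome 7, 88491912 to 88599644), went from 376 FPKM (370 to 390) to 21.6 (19.8 to 23.4). Cpeb4, another gene of this family, was listed at 0 in both GV libraries and had 22.4 FPKM in wild-type MII. Tet3, which oxidises methylated DNA in the zygote, was 18.7-fold higher and the spindle gene Tacc3 was 121-fold lower.

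Other groups were mixed or lower in wild type. Stress and apoptosis genes were lower in 11 of 15 and higher in 3 (median -2.28), with the chaperone gene Hspa8 54.8-fold lower and Trp53 at 1.36 FPKM in GV and 55.8 in MII. Oocyte transcription factors were lower in 7 of 11 and higher in 2 (median -1.17), and Nobox went from 335 to 6.40 FPKM. Reference genes were lower in 9 of 13 and higher in 2 (median -1.82), including Actb at 6.09% and Gapdh at 37.6% of the GV level. Spindle genes were higher in 8 of 22 and lower in 6 (median 0.63), decapping and decay genes higher in 6 of 19 and lower in 7 (median 0.04), and ERK-induced transcripts higher in 3 of 9 and lower in 4 (median 0.00). The medians of CDK1 and cyclins (-0.28; 7 of 22 higher, 9 lower), the anaphase-promoting complex (-0.02; 8 of 27 higher, 12 lower), chromatin modifiers (-0.10; 7 of 22 higher, 9 lower) and the MAPK cascade (-0.44; 5 of 13 higher, 4 lower) turned positive under median-of-ratios scaling. That scaling moved the median of all genes by 0.52 and gave 2745 higher and 4225 lower genes (39.4% of those 2-fold apart higher, against 29.3% as deposited). Of the 8 highest genes 6, and of the 8 lowest 4, were listed at 0 in a library compared (Bola3, 104 FPKM at MII, was listed at 0 at GV), and without genes listed at 0 in any library the lower genes numbered 3196.

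**Figure D2:**
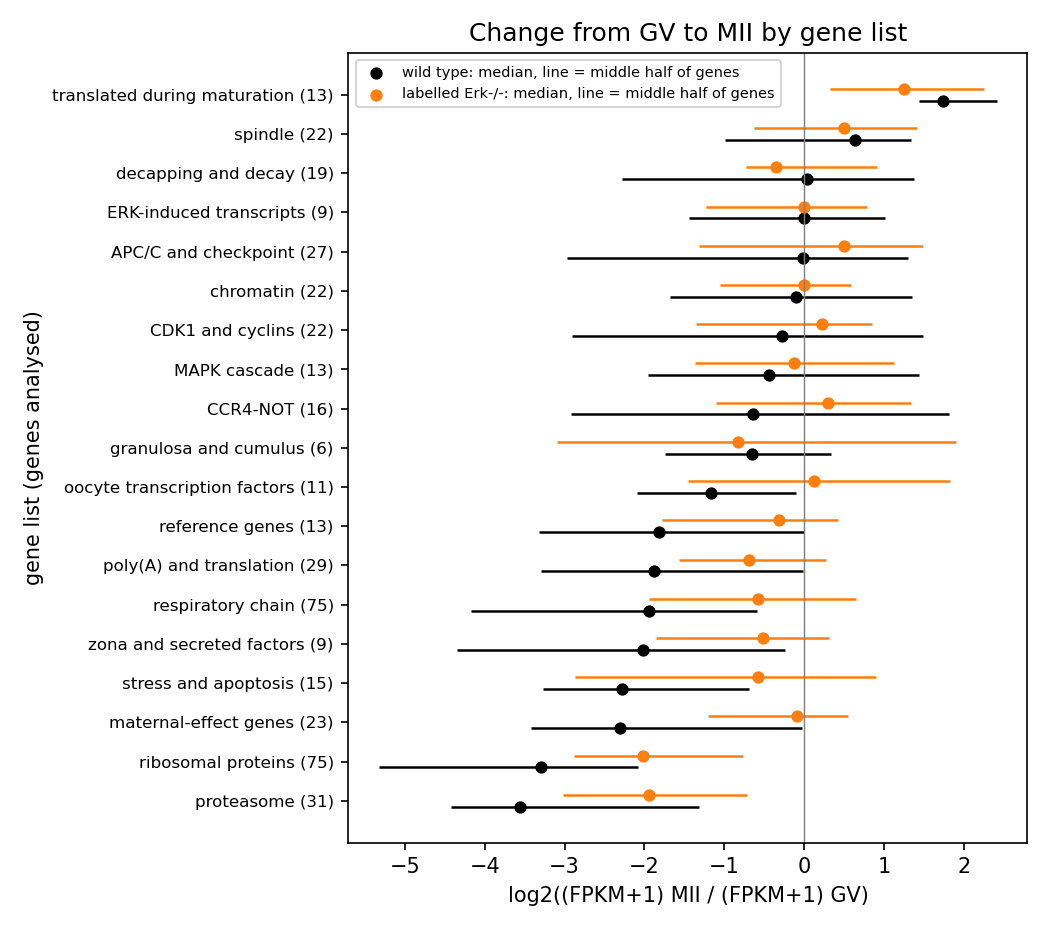
Median log2 ratio of MII to GV for each list with at least 6 analysed genes (points) and the middle part of its genes from the lower to the upper quartile (lines), black wild type and orange labelled Erk-/-. Ribosomal proteins lie at -3.30 and -2.02, and messages translated during maturation at 1.74 and 1.25.

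In oocytes labelled Erk-/-, the egg-coat transcripts and Padi6 were lower at MII than at GV, with more of the GV level left than in wild type. Padi6 stood at 27.5% of its GV level (2641 and 727 FPKM), Zp2 at 24.7%, Zp1 at 27.6% and Zp3 at 14.0%. Nlrp5 (612 and 604 FPKM) and Nlrp14 (1462 and 1461) had nearly equal values at both stages, and Bmp15 was at 124%. Btg4 was at 625% (250 and 1565 FPKM), Cnot7 at 482%, Ccnb1 at 440% and Mos at 312%. Cnot6l, the catalytic subunit gene, had 157 FPKM (150 to 165) at GV and 149 (143 to 156) at MII.

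Over the 9990 genes, 3560 were at least 2-fold lower and 2289 at least 2-fold higher at MII than at GV in the libraries labelled Erk-/- (median log2 -0.26). Maternal-effect genes were lower in 6 of 23 and higher in 3, with a median of -0.09 that turned to 0.02 under median-of-ratios scaling. Ribosomal proteins were lower in 51 of 75 and higher in 5 (median -2.02, percentile 0), with Rpl4 66.1-fold and Rpl19 36.2-fold lower. Proteasome subunits were lower in 21 of 31 and higher in 3 (median -1.94, percentile 0.01), and Psmc2 was 63.7-fold lower. Respiratory chain genes were lower in 31 of 75 and higher in 15 (median -0.58), and -0.30 without genes listed at 0. Messages translated during maturation were higher in 8 of 13 and lower in none (median 1.25, percentile 98.4). Poly(A) and translation factors were lower in 12 of 29 and higher in 3 (median -0.70), zona and secreted factors lower in 3 of 9 and higher in 1 (median -0.51), and stress and apoptosis genes lower in 6 of 15 and higher in 4 (median -0.58, and -1.33 at a mean of at least 10 FPKM). CCR4-NOT genes were higher in 5 of 16 and lower in 4 (median 0.30), the anaphase-promoting complex higher in 10 of 27 and lower in 10 (median 0.49), spindle genes higher in 9 of 22 and lower in 4 (median 0.49), CDK1 and cyclins higher in 4 of 22 and lower in 7 (median 0.22) and reference genes lower in 5 of 13 and higher in 2 (median -0.31). Medians within 0.40 of 0 were also found for chromatin modifiers (-0.01), the MAPK cascade (-0.12), oocyte transcription factors (0.12), decapping and decay (-0.35) and ERK-induced transcripts (0.00). That of chromatin modifiers changed sign under scaling (0.10), and those of the MAPK cascade, oocyte transcription factors and decapping did at a mean of at least 10 FPKM (0.57, -0.83 and 0.23). Of the 5 highest genes 4 were listed at 0 in Erk-/- GV, among them Ifitm3 (183 FPKM in wild-type GV), and without genes listed at 0 in any library 1449 were higher and 2220 lower.

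At MII, where the question of the series lies, many maternal transcripts were higher in the library labelled Erk-/-, in which Mapk3 itself was not lower, than in wild type. Padi6 was 12.4-fold higher (727 and 58.7 FPKM), Nlrp14 16.7-fold (1461 and 87.6), Npm2 9.92-fold and Zp2 5.71-fold. Bmp15 was 3.82-fold, Nlrp5 4.16-fold (604, with bounds 601 to 623, and 145, with bounds 142 to 151) and Cpeb1 3.41-fold higher. Among messages translated during maturation, Btg4 was 1.91-fold lower and Wee2, which holds CDK1 in check in oocytes, 2.93-fold lower (171 and 500 FPKM), Ccnb1 was close (884 and 973), and Dazl was higher (84.7 and 50.3).

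Counted over all genes, 3139 were at least 2-fold higher and 742 at least 2-fold lower in the MII library labelled Erk-/- (median log2 0.31). Maternal-effect genes were higher in 13 of 23 and lower in none (median 1.09, against 0.13 in matched random lists, percentile 98.9), and zona and secreted factors higher in 6 of 9 and lower in none (median 1.82, percentile 99.2). Ribosomal proteins were higher in 42 of 75 and lower in 6 (median 1.34, percentile 100), as with Rps29 (366 and 8.09 FPKM). Respiratory chain genes were higher in 40 of 75 and lower in 3 (median 1.27, percentile 100), and Atp5e was 21.3-fold higher. Proteasome subunits were higher in 14 of 31 and lower in 1 (median 0.89, percentile 97.4), poly(A) and translation factors higher in 13 of 29 and lower in none (median 0.74), and stress and apoptosis genes higher in 8 of 15 and lower in none (median 1.03). Among oocyte transcription factors 5 of 11 were higher and none lower (median 0.82, Lhx8 11.4-fold), as were 5 of 13 reference genes (median 0.92). Actb was 7.18-fold higher and Tubb5 29.4-fold, while Gapdh had 25.9 and 22.2 FPKM, an order that scaling turned. The DNA methylation cofactor gene Dnmt3l was 4.69-fold higher and Uhrf1 had 478 and 159 FPKM among chromatin modifiers, of which 5 of 22 were higher and none lower (median 0.45). Of the 13 messages translated during maturation, 1 was lower and none higher (median -0.44, percentile 1.36). The medians of CCR4-NOT genes (0.13), CDK1 and cyclins (0.06) and the anaphase-promoting complex (0.05) turned negative under scaling, while those of the spindle (-0.02), decapping and decay (-0.11), the MAPK cascade (-0.20) and ERK-induced transcripts (0.00) did not turn.

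**Figure D3:**
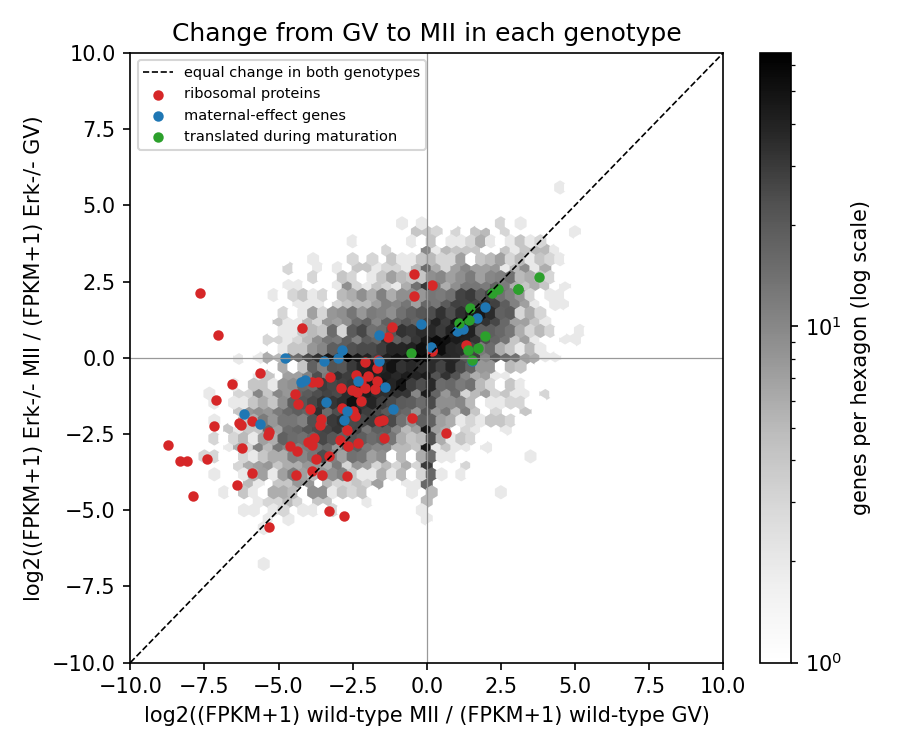
Log2 ratio of MII to GV in wild type (x axis) and in the libraries labelled Erk-/- (y axis) for 9990 genes, grey for genes per hexagon on a log scale, coloured points for members of 3 lists, dashed line for equal ratios. Across genes the ratios correlate with r = 0.518, and many ribosomal protein and maternal-effect genes lie above the dashed line on the lower side.

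Median-of-ratios scaling lowered the median of all genes by 0.31 to 0.00 at MII and gave 2546 higher and 1499 lower genes (62.9% of those apart higher, against 80.9% as deposited). The list medians then stood at 0.66 for maternal-effect genes, 0.92 for ribosomal proteins, 0.83 for the respiratory chain, 0.53 for the proteasome, 0.59 for stress genes, 0.29 for poly(A) and translation factors, 0.47 for reference genes, 0.03 for chromatin modifiers and -0.89 for messages translated during maturation. The spread between the 2 GV libraries was the yardstick for a difference between libraries. In the 2498 genes of highest expression (mean of at least 32.5 FPKM), 95% differed by less than 1.69 log2 units at GV, and 469 genes lay above and 19 below that limit at MII. In wild-type maturation 391 lay above and 828 below it, and in the libraries labelled Erk-/- 294 above and 454 below. Among genes of lower expression the genotypes differed more often at GV. The share 2-fold apart was 61.2% at GV and 35.7% at MII for means up to 3.98 FPKM, and 51.2% and 43.9% up to 11.2. It was 35.2% and 40.7% for means of 11.2 to 32.5 FPKM, and 17.6% and 35.1% above. Over all 9990 genes, 1838 were higher and 2288 lower in Erk-/- at GV, against 3139 and 742 at MII. For means up to 11.2 FPKM, the number apart at MII therefore does not exceed that at GV.

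The maturation ratios of the genotypes were then compared gene by gene, as the ratio in the libraries labelled Erk-/- minus that in wild type, a direction that again rests on an MII library in which Mapk3 was not lower. This difference was at least 2-fold positive for Padi6 (log2 difference 4.30), Nlrp14 (4.78), Npm2 (3.44), Zp2 (3.06), Zp1 (2.49) and Bmp15 (2.33), the transcripts that were lower at MII in wild type. It was negative for several messages that were higher at MII, such as Wee2 (-1.26) and Btg4 (-1.14). It was also negative for Cnot6l (-1.60), in part because Cnot6l was 2.02-fold higher in Erk-/- GV. For Mos (0.18) and Gdf9 (0.10) it lay near 0 and changed sign under scaling. Cdk1, the meiotic kinase gene, had 90.3 FPKM in wild-type GV and 0.0328 in wild-type MII, against 31.5 and 11.4 in the libraries labelled Erk-/-.

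The difference was positive by at least 2-fold in 4120 genes and negative in 1881 (median 0.59). Under median-of-ratios scaling the numbers were 3374 and 2544 (57.0% positive, against 68.7%), with the median of all genes moved by -0.42 to 0.17. Lower in both genotypes were 2664 genes (1765 for independent lists of these sizes), higher in both 1143 (471), lower in wild type and higher in the libraries labelled Erk-/- 447, and the reverse 179. Across genes, which are not independent replicates, the ratios had a Pearson correlation of 0.518 and a Spearman correlation of 0.530, and their SD was 1.83 in the libraries labelled Erk-/- against 2.31 in wild type. In the 4455 genes with a mean ratio of -1 or lower over both genotypes, the median ratio was -2.83 in wild type and -1.68 in the libraries labelled Erk-/-. The median difference was 1.23 (2.35-fold), and it was above 0 in 74.0% of them. Picking genes on the ratio of the libraries labelled Erk-/- alone gave 0.27, and a pseudocount of 0.1 gave 1.89. In the 1915 genes with a mean ratio of 1 or higher the medians were 1.87 and 1.69 and the median difference -0.19.

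By list, the difference was positive by at least 2-fold in 13 of 23 maternal-effect genes and negative in 1 (median 1.53, percentile 99.7). Zona and secreted factors had 5 of 9 positive and none negative (median 2.14), ribosomal proteins 49 of 75 and 6 (median 1.48), respiratory chain genes 46 of 75 and 5 (median 1.497) and proteasome subunits 16 of 31 and 3 (median 1.13). Messages translated during maturation had none positive and 5 of 13 negative (median -0.82, percentile 0.09). Medians were 1.27 for oocyte transcription factors, 1.06 for reference genes, 0.94 for poly(A) and translation factors and for stress genes, 0.67 for the anaphase-promoting complex and -0.23 for ERK-induced transcripts (1.04 with no filter on low values). Those of CCR4-NOT (0.38), the spindle (0.22), chromatin modifiers (0.20), the MAPK cascade (0.18), CDK1 and cyclins (0.14) and decapping (0.00) changed sign under scaling. Scaled medians were 0.999 for maternal-effect genes, 0.95 for ribosomal proteins, 0.99 for the respiratory chain, 0.62 for the proteasome, 0.34 for stress genes and 0.13 for the anaphase-promoting complex. Of the 8 highest single genes 7, and all 8 lowest, were listed at 0 in at least 1 library, and without such genes 2538 were positive and 1101 negative.

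Before maturation, most of the abundant maternal transcripts were within 2-fold between genotypes. In the GV libraries Padi6 had 4264 FPKM in wild type and 2641 in Erk-/-, Zp3 4768 and 3811, Gdf9 4139 and 3611, and Btg4 216 and 250. Nlrp5 had 1172 and 612 and Nlrp14 2427 and 1462. Such gaps at GV enter the difference of maturation ratios. None of the 9 zona and secreted factors and 2 of 23 maternal-effect genes (Hsf1, 3.69-fold higher, and Nlrp9c, 2.66-fold lower in Erk-/-) were 2-fold apart. Respiratory chain genes were lower in 21 of 75 and higher in 9 (median -0.33, percentile 0.08), with Ndufa6 22.6-fold lower (213 and 9.39 FPKM). Of 9 ERK-induced transcripts 2 were higher and 4 lower. The phosphatase gene Dusp4, which ERK signalling induces in somatic cells, was listed at 0 in wild type and had 17.7 FPKM in Erk-/-, and Spry1 was 5.80-fold higher, while Phlda1 had 11.6 FPKM in wild type and 0.262 in Erk-/- and Ier3 had 6.74 in wild type and was listed at 0 in Erk-/-.

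Over all genes, 1838 were at least 2-fold higher and 2288 at least 2-fold lower in Erk-/- GV (median log2 -0.06). The share of genes 2-fold apart was 61.2% in the 2498 genes of lowest expression (mean up to 3.98 FPKM) and 17.6% in the 2498 of highest expression. Other list medians were 0.54 for 6 granulosa and cumulus genes, 0.49 for ERK-induced transcripts, -0.34 for reference genes, -0.20 for zona and secreted factors and for stress genes, -0.19 for the anaphase-promoting complex, -0.18 for maternal-effect genes, -0.15 for oocyte transcription factors, -0.14 for ribosomal proteins, 0.12 for decapping and 0.09 for chromatin modifiers. The proteasome (0.06), translated messages (0.04), CCR4-NOT (-0.09), and the MAPK cascade, spindle, CDK1 and poly(A) lists, whose signs changed under scaling or TPM, lay within 0.10 of 0. Without genes listed at 0 in any library, 966 were higher and 1183 lower, and a pseudocount of 5 gave 1109 and 1393.

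Markers of other cell types were sparse but not absent. Of 26 granulosa and cumulus markers, genes of the cells that surround the oocyte, 6 were analysed, and Amh, Foxl2, Fshr and Star were listed at 0 in all 4 libraries. Nr5a2 had 6.84 FPKM in wild-type GV, 17.0 in Erk-/- GV, 2.24 in wild-type MII and 1.198 in the MII library labelled Erk-/-, and Inha 3.80, 11.3, 0 and 0.0698. Cyp19a1 had 15.5, 0, 21.8 and 10.8 FPKM in the same order. Serpine2 had the highest values of this list in every library (86.2, 79.5, 327 and 337 FPKM in the same order). It was 3.80-fold higher at MII in wild type and within 1.03-fold between the MII libraries. The median of the 6 genes was -0.66 for wild-type maturation, -0.83 for the libraries labelled Erk-/- (0.054 with no filter on low values), 0.02 at MII (negative under scaling) and -0.55 for the difference of maturation ratios. Of 16 markers of stroma, endothelium and blood, 2 were analysed, Pecam1 (25.6, 42.9, 48.6 and 64.3 FPKM in the same order) and Cd68 (0, 0, 1.58 and 6.79). None of the 18 early-embryo genes was analysed, with Zscan4f at 1.62 FPKM and Zscan4c at 1.27 in wild-type GV and 0 elsewhere.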

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

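All tests in this part were chosen after the results were seen. Each result below was picked out because its maturation ratio pointed in opposite directions in the 2 genotypes, and none of these differences was tested, since each group has 1 library. The CCR4-NOT list had a median log2 ratio of MII to GV of -0.64 in wild type and 0.30 in the libraries labelled Erk-/-, a difference of 0.94. Under median-of-ratios scaling the medians were -0.0046 and 0.39, so the opposite directions depend on the scale. The list holds genes of both directions in wild type (Cnot7 and Cnot6l higher, Cnot1 lower), so its median depends on a few genes in the middle.

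Rpl38, a ribosomal protein gene whose reads may be shared with pseudogenes, had 354 FPKM in wild-type GV, 38.7 in Erk-/- GV, 0.768 in wild-type MII and 172 in the MII library labelled Erk-/-, a difference of maturation ratios of 9.77 that was not tested. Ndufa6, of respiratory complex I, had 213, 9.39, 10.2 and 76.4 FPKM in the same order (difference 7.15). Psmd11, of the proteasome, had 0.173, 53.3, 11.1 and 13.2 FPKM (difference -5.29). In Ndufa6 and Psmd11 the low GV value of 1 genotype makes most of the difference.

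Single low GV values may be failed detection rather than absent mRNA. Genes at 0 in Erk-/- GV and at 10 FPKM or more in wild-type GV numbered 224, and 176 the other way round. Oocytes make almost no mRNA between the stages, so a gene truly absent at GV should stay absent at MII of the same genotype. Of such genes also at 10 FPKM or more in the other genotype's MII library, 24 of 26 (92.3%) had at least 1 FPKM in the MII library labelled Erk-/- and 18 of 23 (78.3%) in wild-type MII, against 99.9% and 94.6% of genes present at GV. The test is met for failed detection in most of these 26 and 23 genes, although renewed polyadenylation of untailed mRNA would give the same values. The rest of the 224 and 176 genes, under 10 FPKM in the other genotype's MII library, were not tested.

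The smaller maturation differences in the libraries labelled Erk-/- could come, among other causes, from GV-stage oocytes mixed into the MII sample, from scaling, or from less degradation. The labels do not say whether mRNA was selected by its poly(A) tail, so a lower FPKM does not by itself show degradation. Mixing alone would leave strongly lowered genes at about the same share of their GV level. The spread of that share was therefore predicted to be near the spread between the GV libraries. In 489 genes at least 8-fold lower in wild-type MII, with at least 50 FPKM in both GV libraries, the ratio of these spreads was 2.79 (2.51 to 3.23 in 1000 resamplings of genes), where up to 1.5 was predicted for mixing. The limit on FPKM narrows the GV spread, and the ratio was 1.93 with at least 10 FPKM (1390 genes) and 3.35 with at least 200 (107 genes). The share kept ran from 5.20% to 52.4% between the 10th and 90th percentiles (median 19.2%, against 3.61% in wild type). Because these genes were picked for being at least 8-fold lower in wild type, the wild-type median is low by selection. The gap between these medians therefore does not measure a genotype difference. The ratio was above the limit predicted for mixing, but this cannot exclude mixing as the whole cause. Genes of lower expression differed more between the GV libraries, and the MII values used here are lower than the GV values. The share left in wild-type MII also varied, up to 9.50% at the 90th percentile, and would widen the spread under mixing. After median-of-ratios scaling the median difference in 3905 lowered genes was 0.96, so 1 factor per library does not account for the smaller differences. The implied log2 depth of wild-type MII minus the other MII library was 0.0498, so lower depth does not either. That depth rests on 2500 genes above 5 FPKM in every library and cannot show failed detection of other genes. Listed at 0 were 1881 analysed genes in wild-type MII and 733 in the MII library labelled Erk-/-. Failed detection in wild-type MII was not tested. Without genes listed at 0 in any library the median difference was 1.17 (2761 genes).

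That loss of ERK slows mRNA degradation stays an untested hypothesis, because 1 library per group cannot separate genotype from batch, from an exchange of samples or from the exact hour of collection. The share of GV material implied by 673 genes that are higher at MII varied widely (median 32.2%, quartiles 13.1% and 45.7%). It does not tell a delay in maturation from partial mixing. Replicate libraries of both genotypes with spiked-in RNA would show whether the difference repeats and would give amounts per oocyte. Reads over the deleted exons would check the genotype label. Neither would by itself tell a delay in maturation from slower degradation.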

How the results depend on the processing

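The run without genes listed at 0 and the run on the mean of both GV libraries were added after the results were seen, and the other alternatives were planned. No paired analysis was possible because each group has 1 library and the labels name no pairs. A result counted as moved when a number of genes altered more than 1.5-fold or a list median by more than the SD of medians of random lists of that size, and as reversed when a value of at least 2-fold turned direction. Of counts and summaries 89 stayed and 27 moved, of list medians 624 stayed and 44 moved, of values of named genes 3472 stayed and 744 moved, and none reversed.

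The median difference of maturation ratios (labelled Erk-/- minus wild type) in genes lower at MII was 1.23. Picking the genes on the ratio labelled Erk-/- alone gave 0.27, since genes picked on 1 of the ratios are drawn towards extremes of that ratio, and on the wild-type ratio alone 1.72. A pseudocount of 0.1, which widens ratios of low genes, gave 1.89, and moved poly(A) and translation factors in wild-type maturation to -2.53.

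A pseudocount of 5 shrinks ratios of low genes by construction. It gave 1372 genes higher in maturation labelled Erk-/-, 1109 higher and 1393 lower for Erk-/- against wild type at GV, and 1548 higher and 293 lower at MII. At MII the medians stood at 0.91 for the respiratory chain, 1.15 for ribosomal proteins and 0.43 for stress genes. In wild-type maturation they stood at -2.76 for ribosomal proteins, -2.57 for the proteasome and -1.32 for stress genes, and for the difference of maturation ratios at 0.996 for the respiratory chain.

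A mean of at least 10 FPKM leaves 5294 genes, and the smaller numbers follow from fewer genes. Wild-type maturation had 1218 higher and 2553 lower, maturation labelled Erk-/- 1170 and 1854, genotype at GV 647 and 788, genotype at MII 1754 and 281, and the difference of maturation ratios 2070 and 742. The MAPK cascade then had medians of 1.18 in wild-type and 0.57 in maturation labelled Erk-/-, poly(A) factors -0.96 in wild type, and decapping, oocyte transcription factors and stress genes 0.23, -0.83 and -1.33 in maturation labelled Erk-/-. These lists lose members, and the cause was not tested further. With no filter, ERK-induced transcripts had a difference of 1.04 and granulosa and cumulus genes 0.054 in maturation labelled Erk-/-, with more members near 0.

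Median-of-ratios scaling multiplies each library by 1 factor, which moved the medians below; with the added 1 the shift differs between genes. Lower genes at MII in the library labelled Erk-/- numbered 1499. Medians at MII were -0.33 for CCR4-NOT, -0.45 for decapping, 0.29 for poly(A) factors, 0.66 for maternal-effect genes, -0.38 for CDK1 and cyclins, -0.36 for the anaphase-promoting complex, -0.46 for the spindle, -0.89 for messages translated during maturation, 0.83 for the respiratory chain, 0.92 for ribosomal proteins, 0.53 for the proteasome, 0.035 for chromatin modifiers, 0.59 for stress genes and 0.47 for reference genes. For the difference of maturation ratios they were 0.999 for maternal-effect genes, 0.13 for the anaphase-promoting complex, -0.31 for the spindle, 0.99 for the respiratory chain, 0.95 for ribosomal proteins, 0.62 for the proteasome and 0.34 for stress genes. In wild-type maturation the respiratory chain had -1.33 and ribosomal proteins -2.80.

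Without genes listed at 0 in any library 6967 genes remain. Lower in wild-type maturation were 3196, higher and lower in maturation labelled Erk-/- 1449 and 2220, at GV 966 and 1183, at MII 1980 and 428, and for the difference of maturation ratios 2538 and 1101, again from fewer genes. In maturation labelled Erk-/- ERK-induced transcripts had a median of 0.75, decapping 0.23 and the respiratory chain -0.30. The respiratory chain had 1.01 at MII, and decapping -0.58 for the difference of maturation ratios. The cause of these moved medians was not tested. With the mean of both GV libraries as baseline, 1833 genes were higher and 5322 lower in wild-type MII, 1678 and 4027 in the MII library labelled Erk-/-, and the median difference in lowered genes was 0.92.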

Other observations

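The gene families in this part and all tests but the 2 on CPE motifs were chosen after the results were seen. The families were picked from a scan of 77 families of at least 12 genes that share the start of their symbol. Some extreme percentiles would arise in such a scan by chance alone, so they carry little weight. Transcripts for the mitochondrial ribosome were lower at MII in wild type. Of 46 Mrpl genes 33 were lower and 4 higher (median log2 -2.77, percentile 0.10 among 2000 matched random lists), and Mrpl14 went from 669 to 93.4 FPKM. Initiation factor genes, which load ribosomes onto mRNA, had 31 of 50 lower and 7 higher (median -2.31, percentile 0.05). Eif3g (162 and 0.197) and Eif6 (195 and 14.7) were lower, while Eif5a (308 and 568) and Eif2b1 (91.2 and 348) were higher. DEAD-box helicases had 23 of 34 lower and 3 higher (median -2.68), though Ddx3x, which unwinds 5' UTRs, was higher (151 and 632).

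Centrosomal protein genes were mixed in wild type, with 11 of 27 higher and 10 lower (median 0.43, percentile 99.7). Cep55, of the cytokinetic bridge, had 19.0 FPKM at GV and 107 at MII. Palmitoyltransferase genes of the Zdhhc family had 7 of 14 higher and 4 lower (median 0.79). Of 12 Kdm histone demethylase genes 5 were higher and 3 lower in wild type, and 5 higher and 1 lower in the libraries labelled Erk-/-. The 2 that remove H3K27 methylation were higher in both, with Kdm6b at 21.9 and 161 FPKM in wild type and 40.2 and 106 in the libraries labelled Erk-/-, and Kdm6a at 15.4 and 120, and 19.9 and 68.5. In the libraries labelled Erk-/- the Mrpl genes had a median of -0.68 (percentile 17.85) and initiation factors -1.14 (percentile 0).

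Higher values at MII could come from a gain of poly(A) tail before mRNA purification or from unaltered transcripts in a shrinking total. The first was tested with the cytoplasmic polyadenylation element (CPE, TTTTAT or TTTTAAT in the last 100 nt of the 3' UTR), a prediction written before the values were compared. In wild type 1782 genes with a CPE, of 8783 searched, had a median log2 ratio of 0.17, against -0.87 in matched random lists (percentile 100), -0.40 in lists matched on GC content, and -0.68 in 1293 genes with only a control motif of the same bases. The control genes were themselves at percentile 99.8 of their random lists (-0.96), so part of the excess is shared with a motif that is not a CPE. The excess over the control fits tail gain, and equally fits a slower loss of CPE-bearing mRNA. The median of 1.87 over the 1915 higher genes cannot tell either from a shrinking total, because no amounts per oocyte were measured.

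If ERK promoted polyadenylation at CPEs, such genes would be expected to gain less, relative to other genes, in the libraries labelled Erk-/-. Their median difference of maturation ratios was 0.11, at percentile 0 of matched random lists (0.55; 0.42 when matched on GC content and 0.30 when matched on the mean maturation ratio). As deposited, the median ratio itself was 0.31 in the libraries labelled Erk-/- against 0.17 in wild type. On that scale their gain was not smaller in itself, and the hypothesis may hold only in the relative form that the percentile tests. Median-of-ratios scaling moved the median difference of all genes by -0.42. It was not applied to the CPE genes, and a shift of that size would turn the order of 0.31 and 0.17. An even compression of all maturation ratios would have given about the 0.30 of genes with the same mean ratio, so it does not account for the whole difference, and an uneven difference between single libraries stays open. Poly(A) tail lengths measured in replicate oocytes would separate these.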
